A study of Homo sapiens with 57 samples.

How the data were processed

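RNA from 57 human samples was measured on Affymetrix arrays after whole-transcript labelling, per the labels' protocols. The array model was not given in the sources used here. The samples came from kidney transplant recipients monitored for BK virus (BKV), a polyomavirus that persists in the urinary tract and can replicate in a graft under immunosuppression. Per the labels, 40 arrays held whole blood collected in RNA-stabilizing tubes, and 17 held a needle core of the graft. Per the labels, viremia meant at least 1000 viral copies per ml of plasma in 2 consecutive tests. Nephropathy was diagnosed, per the labels, from viral inclusions and a positive SV40 stain.

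The values analysed were the deposited log2 values, 1 per probe set and sample. The authors made them with RMA in the oligo package, per the submitters' processing notes, which also name limma. RMA by design corrects background, applies quantile normalization and summarizes the probes of a set by median polish. Versions of these tools, the genome build and the dates of scanning were not given in the sources used here, so no scan batch could be tested. The medians of the samples lay between 6.46 and 6.65 in blood and between 7.00 and 7.11 in biopsies. Medians and upper quartiles did not overlap between tissues, while lower quartiles did (5.01 to 5.54 in blood, with control blood 11 highest, and 5.36 to 5.65 in biopsies). Values were compared within a tissue only. A test of whether the effect of viremia differed between tissues was planned only for tissues on 1 scale and was not run.

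The table held 29096 probe sets. The annotation gave 1 gene symbol to 19460 of them, several symbols to 1754 and no gene to 7882. Of those with 1 symbol, 19429 were matched to a current gene by Entrez identifier and 31 kept the annotation's own symbol. Probe sets of XIST, TSIX and genes of the Y chromosome (95) were removed before any fit. Where a gene had several probe sets, the one with the highest mean in the tissue was kept, which left 18394 genes.

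The labels put the samples into 6 groups. Blood held 19 samples at viremia, 7 taken 1 to 2 months before viremia, and 14 controls from recipients with stable grafts and no viremia. Biopsies held 3 with BKV nephropathy, 3 of normal histology with virus in the blood (called BKV-positive normal), and 11 normal biopsies, which per the labels include mild fibrosis with tubular atrophy. Each pair of groups within a tissue was compared, which makes 6 comparisons. Genes were tested with limma 3.58.1 in R 4.3.3 with data.table version 1.17.8 (eBayes defaults), with the 3 groups of a tissue in 1 fit. Tests were two-sided, with Benjamini-Hochberg adjustment over the 18394 genes and a threshold of 0.05 on the adjusted p. The ± beside a log2 difference of a gene is limma's standard error, and ± beside a level is the SD over samples. The 12 largest rises of each nephropathy comparison were checked for a level among the dimmest 25% of genes in the comparison group. Where a gene lay there, its difference may understate the rise, which was not tested. Other named rises were not marked in this way.

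Before the data were examined, 35 gene lists, the rule for the genes named and the alternatives to try were fixed. The lists cover cell types of blood and kidney, interferon responses, cell cycle, stress, nephron segments, injury, matrix and complement. A list's score in a sample is the mean log2 value of its measured members. The difference of group means was tested two-sided by permuting samples, exactly where a group had fewer than 10 samples and otherwise with 100000 resamples, and adjusted over the 35 lists. Counts of members past the threshold are given over all genes and adjusted over the list alone. As another list test, camera was run with its preset correlation of 0.01 and with an estimated correlation.

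The genes named were, per comparison, the 12 with the largest rise and the 12 with the largest fall among those past the threshold. Where fewer than 10 passed, those with the smallest unadjusted p were named, up to 10 in all. From each list described, up to 4 members with the smallest p were named. All 35 lists are described for nephropathy against normal biopsies. Which lists are described in the other comparisons was chosen after their values were seen. CXCR5, CCL21, LAMP3, LTB, CR2 and FDCSP were also chosen after their values were seen. Immunoglobulin and T cell receptor segments, KIR genes, classical HLA genes and genes lost in common deletions stayed in the fits and were not named.

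The sample codes carry a number. Among the 40 blood samples there were 34 distinct numbers, and among the 17 biopsies 16, although the series describes 40 patients for the blood. Of 6 pairs of blood samples with 1 number, 5 joined a sample at viremia to a sample before viremia. Their deviations from the group means correlated across genes at 0.218 to 0.663, and all 5 exceeded 0.1, as did 238 of 746 blood pairs sharing neither number (highest 0.771). The number is therefore taken to pair these samples, without certainty. The other blood pair, a control and a sample before viremia, correlated at 0.0917, and the 1 pair of normal biopsies at −0.0335. Of pairs sharing only the number in the title, 13 of 28 in blood and 6 of 9 in biopsies exceeded 0.1, and that number is not known to pair samples. In a check for mixed-up samples, 0 of 7 pairs differed in sex-linked expression. A random block on the code number was fitted in blood (consensus correlation 0.29) and could not be estimated in biopsies. Nothing in the labels rules out that p-values measure only the spread between these samples.

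The tests were run on simulated data with 200 changed genes among 18394 (50 at each of 4 sizes), drawn from the genes' means and residual SDs. At a log2 change of 1, limma recovered 100% of the changed genes for viremia against control, 96% for before viremia against control and 92% for viremia against before viremia. It recovered 90% for nephropathy against normal, 90% for BKV-positive normal against normal and 76% for nephropathy against BKV-positive normal. At a change of 0.5 the values were 80%, 62%, 58%, 44%, 46% and 30%, in that order, with 12, 7, 11, 9, 7 and 9 false calls among unchanged genes. With 5 lists shifted, the list test called 5, 5, 5, 5, 4 and 0 of them, and called 0, 3, 2, 0, 0 and 0 unshifted lists. Each gene was drawn independently, so the simulation leaves out correlation between genes. Its recovery and false calls, above all those of lists, need not hold for these data. The number of arrays limits the precision of every comparison.

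Alternatives tried for gene counts were leaving out the dimmest 25% of genes, the mean of a gene's probe sets, every probe set tested, repeated quantile normalization, eBayes with trend and robust, array quality weights, and only the compared groups in the fit. Others were blocks on the title number and the code number, leaving out samples whose code number recurs, neutrophil and erythroid list means as covariates in blood, and leaving out each sample in turn. Lists were also scored by the median and with members scaled to unit SD. Leaving out control blood array 11, leaving out normal biopsy 6 and limma on list means were added after seeing the data, as were the draws and blood splits without array 11, the draws keeping code pairs, the draws for the nephropathy genes in blood, those genes with normal biopsies divided, and the plasma cell list without JCHAIN. Correlations between comparisons with shared controls were set beside 100 draws in which group labels were permuted over the samples' deviations from their group means, and beside values with the controls divided at random between both comparisons. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.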

Results

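The series holds genome-wide RNA profiles of 40 whole-blood samples and 17 graft biopsies from kidney transplant recipients, in 6 groups defined by BKV status. Blood groups numbered 19 at viremia, 7 taken 1 to 2 months before viremia and 14 controls. Biopsy groups numbered 3 with nephropathy, 3 BKV-positive normal and 11 normal. Arrays of a tissue resembled each other, with each array's median correlation to the others at 0.962 or above in biopsies. The lowest was that of normal biopsy 6, below the nephropathy biopsies at 0.964 to 0.967. Its highest correlation with another biopsy was 0.972, against 0.984 or more for every other biopsy. In blood 1 array stood apart, control blood 11, whose median correlation to the others was 0.897.

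The first question was what distinguishes a graft with BKV nephropathy from a normal graft. Against 11 normal biopsies, nephron transcripts decreased in the 3 nephropathy biopsies. The distal nephron list passed and the proximal tubule list did not, although single proximal genes fell too. The same biopsies carried a broad increase of lymphocyte and macrophage transcripts, of interferon-inducible genes and of cell cycle genes. In camera with an estimated correlation both interferon lists lost their call (adjusted p = 0.0765 and 0.123), and the type I interferon-stimulated list did not pass the permutation test without nephropathy biopsy 2 (0.97, adjusted p = 0.0561). Of 18394 genes, 2251 rose and 1807 fell (limma, adjusted p under 0.05), and among them 762 rose and 261 fell by more than 2-fold. Leaving out any 1 nephropathy biopsy, which leaves fewer samples, lowered the number of falls more than that of rises. Of the genes, 1821 rose and 997 fell without nephropathy biopsy 1, 1632 and 969 without biopsy 2, and 1696 and 1110 without biopsy 3. The largest measured rise was in CXCL13, the chemokine that draws B cells into lymphoid follicles, from 4.38 ± 0.66 to 9.18 ± 0.73 on the log2 scale (difference 4.81 ± 0.37, higher in 3 of 3, adjusted p = 1.26e-07). Its level in normal biopsies is low on the array's scale, with 3.55% of genes below it, so this difference may understate the rise. The largest fall was in SLC7A13, an amino acid transporter of the proximal tubule, which fell by 4.08 ± 0.74 (lower in 3 of 3, adjusted p = 0.000592).

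B-lineage genes were prominent among the largest rises. JCHAIN, which joins secreted IgA and IgM, was 4.24 ± 0.84 higher, MS4A1 (CD20) 4.04 ± 0.55 and CD79A, a signalling chain of the B cell receptor, 3.55 ± 0.35. Of the 11 measured B cell list members 10 rose, and 11 adjusted over the list alone. The list mean went from 6.29 ± 0.21 to 8.11 ± 0.55 (3.53-fold). CD22 rose by 2.75 ± 0.30, BANK1 by 1.86 ± 0.22 and FCRLA by 1.66 ± 0.14. Of 9 plasma cell members 7 rose (7 higher and 1 lower adjusted over the list alone), among them TNFRSF17, the plasma cell survival receptor BCMA, by 1.83 ± 0.20, FCRL5 by 1.77 ± 0.22, POU2AF1 by 1.38 ± 0.17 and DERL3 by 1.24 ± 0.15. The plasma cell list difference was 1.56. In both lists the 3 nephropathy biopsies lay above all normal ones, and the exact permutation p of 0.00275 (adjusted p = 0.00437) is the smallest that the 364 splits can give.

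T cell genes rose as a block. All 14 measured members of the T cell list rose, over all genes and adjusted over the list alone. The list mean went from 6.76 ± 0.40 to 9.04 ± 0.09 (4.86-fold). CD4 rose by 2.53 ± 0.21, the costimulatory receptors ICOS and CD28 by 2.65 ± 0.25 and 2.27 ± 0.22, and UBASH3A by 1.71 ± 0.14. TRAT1, an adaptor of the T cell receptor, was among the 12 largest rises at 3.42 ± 0.43, as were SLAMF6 at 3.30 ± 0.48, SLAMF7 at 3.49 ± 0.53, PLAC8 at 3.61 ± 0.41 and the hematopoietic microRNA gene MIR142 at 3.47 ± 0.39. TRAT1 and MIR142 lie in the dimmest 25% of genes in normal biopsies, so their differences may understate the rise. Of 7 naive and memory T cell members 4 rose and 1 fell (5 and 1 adjusted over the list alone), led by the lymph node homing receptor CCR7 (3.28 ± 0.24) and the interleukin-7 receptor IL7R (3.40 ± 0.49), with LEF1 at 1.79 ± 0.22 and BCL11B at 0.79 ± 0.13. Of 8 inhibitory receptor members 6 rose (7 adjusted over the list alone), among them CTLA4 by 1.64 ± 0.12, TIGIT by 1.73 ± 0.17 and CD244 by 1.18 ± 0.17. Of the 15 cytotoxic members 14 rose (14 adjusted over the list alone), including CD8A by 1.84 ± 0.33, IFNG by 1.37 ± 0.23, GNLY by 1.26 ± 0.14 and GZMB by 1.07 ± 0.18. The cytotoxic list difference was 1.40, and in camera its adjusted p = 0.103 with an estimated correlation. Of 11 NK cell members 6 rose (7 adjusted over the list alone), such as KLRB1 by 2.50 ± 0.20, XCL1 by 1.82 ± 0.24, CD160 by 1.15 ± 0.24 and NCR3 by 0.57 ± 0.14, with a smaller list difference of 0.69. Each of these 5 lists had the smallest possible p, with 3 of 3 nephropathy biopsies above all normal ones. NCR3 did not pass without nephropathy biopsy 2 (13 of 163 named genes lost their call there).

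**Figure D1:**
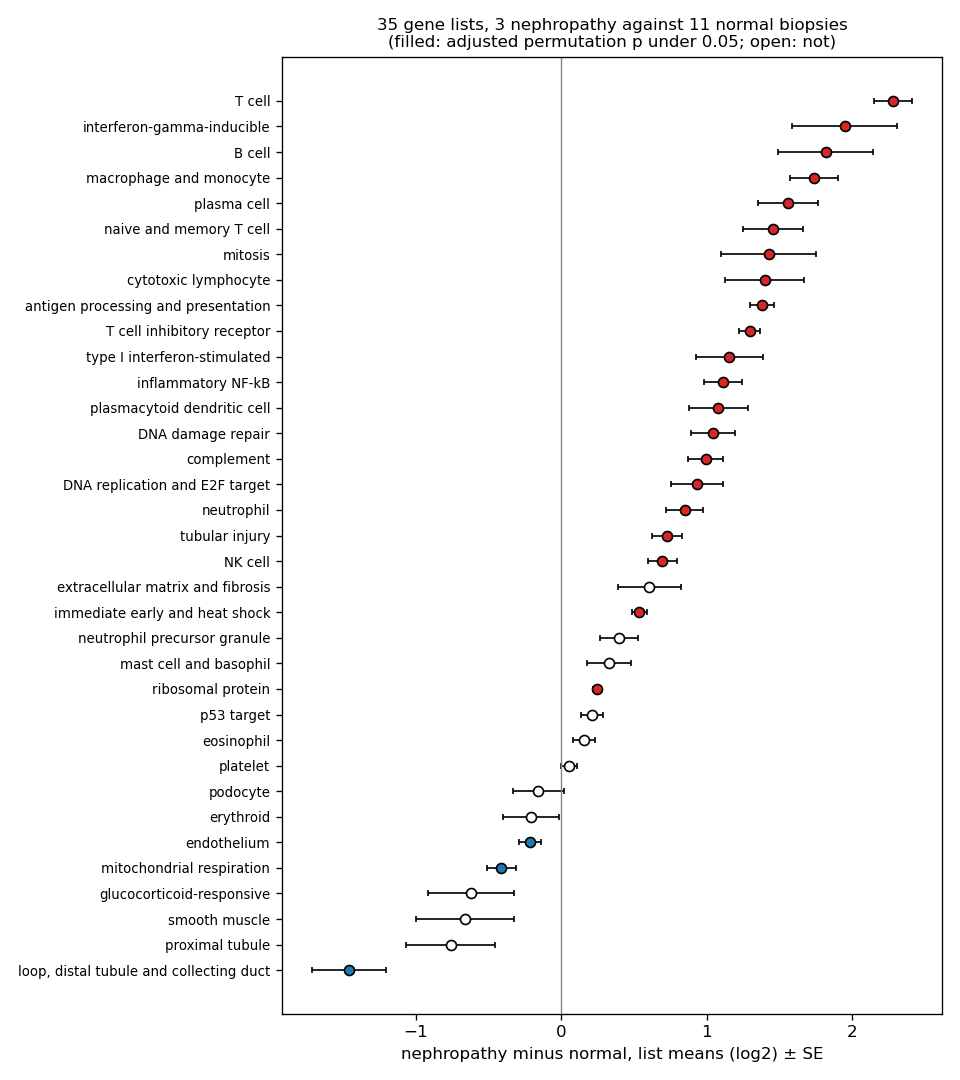
Difference of the list means between 3 nephropathy and 11 normal biopsies, on the log2 scale, for each of the 35 gene lists; bars are the SE of the difference, and filled points passed the permutation test after adjustment. The T cell list lies farthest to the right, at 2.28, and the loop, distal tubule and collecting duct list farthest to the left, at −1.46.

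Macrophage and interferon genes moved with the lymphocyte genes. Of 16 macrophage and monocyte members 15 rose (16 adjusted over the list alone), including the growth factor receptor CSF1R by 1.73 ± 0.17, CD86 by 2.36 ± 0.26, FCER1G by 2.40 ± 0.29 and the scavenger receptor CD163 by 1.87 ± 0.24. The list rose 3.33-fold. All 13 interferon-gamma-inducible members rose (13 adjusted over the list alone), with GBP5 higher by 3.28 ± 0.53, the tryptophan-degrading enzyme IDO1 by 3.20 ± 0.54, IRF1 by 1.91 ± 0.30 and CIITA, the regulator of HLA class II genes, by 1.07 ± 0.15. That list's difference was 1.95, and in camera its adjusted p = 0.0765 with an estimated correlation. All 12 antigen processing and presentation members rose (12 adjusted over the list alone), such as PSMB9, a subunit of the immunoproteasome, by 1.88 ± 0.23, PSMB10 by 0.96 ± 0.11, HLA-DOA by 1.45 ± 0.18 and HLA-DMA by 1.39 ± 0.18. Of 23 type I interferon-stimulated members 18 rose (20 adjusted over the list alone), among them OAS2 by 2.26 ± 0.34, EPSTI1 by 1.82 ± 0.27, OAS3 by 1.81 ± 0.29 and SIGLEC1 by 0.99 ± 0.16. The difference of 1.16 had an exact permutation p of 0.00824 (adjusted p = 0.0125), and in camera its adjusted p = 0.123 with an estimated correlation. Without nephropathy biopsy 2 the type I interferon-stimulated list difference was 0.97 and did not pass (adjusted p = 0.0561, exact permutation test). Of 14 inflammatory NF-kB members 11 rose (14 adjusted over the list alone), including the inhibitor TNFAIP3 by 2.03 ± 0.23, IL1B by 1.79 ± 0.23, TNF by 1.30 ± 0.14 and CXCL1 by 1.13 ± 0.12. The macrophage, interferon-gamma-inducible, antigen presentation and NF-kB lists had the smallest possible p, with 3 of 3 biopsies higher.

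Cell cycle genes rose in nephropathy. Of 20 mitosis members 18 rose (20 adjusted over the list alone), with cyclin CCNB2 higher by 2.36 ± 0.22, CDK1 by 1.71 ± 0.21, NUSAP1 by 1.71 ± 0.19 and CENPF by 1.59 ± 0.18. The mitosis list mean went from 5.88 ± 0.24 to 7.30 ± 0.55. Of 25 DNA replication and E2F target members 21 rose (24 adjusted over the list alone), including the replication licensing factor CDC6 by 2.47 ± 0.21, the ribonucleotide reductase subunit RRM2 by 2.34 ± 0.23, the S phase cyclin CCNE2 by 1.96 ± 0.20 and UHRF1 by 1.58 ± 0.17. Of 11 DNA damage repair members 9 rose (10 adjusted over the list alone), led by the helicase BLM at 1.85 ± 0.13, with RAD51AP1 at 1.71 ± 0.17, FANCI at 1.67 ± 0.16 and XRCC2 at 1.07 ± 0.13. The 3 lists had the smallest possible p. Of 11 p53 targets 3 rose, over all genes and adjusted over the list alone, TNFRSF10B by 0.57 ± 0.10, FAS by 0.83 ± 0.20 and BAX by 0.42 ± 0.11. The p53 list did not pass (difference 0.21, higher in 3 of 3, adjusted p = 0.0687, exact permutation test), but did without normal biopsy 6 (0.24, adjusted p = 0.035) or 1 (0.23, adjusted p = 0.0499). BAX did not pass without nephropathy biopsy 2, where 13 of 163 named genes lost their call.

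Transcripts of the distal nephron fell. Of 15 loop, distal tubule and collecting duct members 12 fell (13 adjusted over the list alone). The list mean went from 9.98 ± 0.32 to 8.52 ± 0.41. EGF, the growth factor of the thick ascending limb and distal tubule, fell by 3.30 ± 0.58. The collecting duct water channel AQP2 fell by 2.32 ± 0.37, the sodium channel subunit SCNN1B fell by 1.52 ± 0.25 and the potassium channel KCNJ1 fell by 1.45 ± 0.21. Other large falls were in genes that are members of neither this list nor the proximal tubule list. Their nephron segment was not examined, so they are not counted as distal. They were MUC15 (−2.75 ± 0.40), UPP2 (−2.51 ± 0.41), HRG (−2.43 ± 0.44), PLG (−2.35 ± 0.57), RANBP3L (−2.32 ± 0.51), GSTA2 (−2.32 ± 0.65), F11 (−2.31 ± 0.35), TMEM207 (−2.29 ± 0.51) and the transporter SLC23A3 (−2.24 ± 0.48). PLG did not pass without nephropathy biopsy 1, nor GSTA2 without nephropathy biopsy 1 or 2, where 16 and 13 of 163 named genes lost their call.

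Of 18 proximal tubule members 4 fell, over all genes and adjusted over the list alone. These were FBP1 (−1.22 ± 0.36), MIOX (−1.32 ± 0.42), GATM (−0.74 ± 0.20) and the water channel AQP1 (−0.51 ± 0.16). The proximal list itself did not pass (difference −0.76, lower in 3 of 3, adjusted p = 0.105, exact permutation test), but did without normal biopsy 6 (−0.96, adjusted p = 0.0051). Each of those 4 genes also lost its call without at least 1 nephropathy biopsy (16, 13 and 7 of 163 named genes without biopsy 1, 2 and 3). None of 9 podocyte members passed, over all genes or adjusted over the list alone. The podocyte list difference was −0.16 (lower in 2 of 3, adjusted p = 0.464, exact permutation test), with PODXL at −0.33 ± 0.20, CLIC5 at −0.29 ± 0.22, PLA2R1 at −0.29 ± 0.26 and TCF21 at −0.20 ± 0.21. The podocyte difference was −0.30 without nephropathy biopsy 2 and −0.06 without biopsy 3, where TCF21 differed by 0.12.

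Of 19 mitochondrial respiration members 11 fell (15 adjusted over the list alone), such as NDUFS1 (−0.66 ± 0.12), NDUFS4 (−0.57 ± 0.14), SDHD (−0.49 ± 0.11) and ATP5F1B (−0.33 ± 0.08). The mitochondrial list difference of −0.41 had the smallest possible p, and in camera its adjusted p = 0.124 with an estimated correlation. In the endothelium list 5 of 12 members fell and 1 rose (5 lower and 2 higher adjusted over the list alone). TEK changed by −0.82 ± 0.16, EMCN by −0.78 ± 0.16, FLT1 by −0.63 ± 0.17 and ENG by 0.36 ± 0.10. The endothelium list difference was −0.21 (lower in 3 of 3, adjusted p = 0.0401, exact permutation test), and in camera its adjusted p = 0.404 with an estimated correlation. It did not pass without nephropathy biopsy 1 (−0.21, adjusted p = 0.069), nephropathy biopsy 3 (−0.16, adjusted p = 0.135) or normal biopsy 10 (−0.21, adjusted p = 0.051). ATP5F1B, FLT1 and ENG lost their calls without nephropathy biopsy 1, and FLT1 and ENG also without biopsy 2 (16 and 13 of 163 named genes).

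Injury and matrix genes were higher in part. Of 18 tubular injury members 8 rose (10 adjusted over the list alone), among them the hyaluronan receptor CD44 by 1.68 ± 0.18, TIMP1 by 1.41 ± 0.19, LCN2 by 1.41 ± 0.25 and CXCL16 by 1.25 ± 0.17. The tubular injury list difference was 0.73 with the smallest possible p, and in camera its adjusted p = 0.132 with an estimated correlation. CD44, TIMP1, LCN2 and CXCL16 are expressed by leukocytes as well as by tubules. Of 19 extracellular matrix members 7 rose, over all genes and adjusted over the list alone, including VCAN by 1.94 ± 0.47, TGFBI by 1.20 ± 0.22, TGFB1 by 1.13 ± 0.17 and the collagen COL4A1 by 0.68 ± 0.16, with VCAN lost without nephropathy biopsy 1. The matrix list did not pass (difference 0.61, higher in 3 of 3, adjusted p = 0.0696, exact permutation test), but did without normal biopsy 6 (0.69, adjusted p = 0.0181) or 1 (0.67, adjusted p = 0.0392).

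Of the 35 lists, 21 rose and 3 fell by the permutation test, and 15 passed in camera with an estimated correlation. Of 163 genes named or followed in this comparison, 20 lost their call when 1 biopsy was left out, 16 of them without nephropathy biopsy 1. The gene count was 2601 without nephropathy biopsy 2, and 7000 with array quality weights, of which 3311 rose and 3689 fell. With the title number as a block, which is not known to pair samples, 2159 genes passed, of which 1378 rose and 781 fell.

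**Figure D2:**
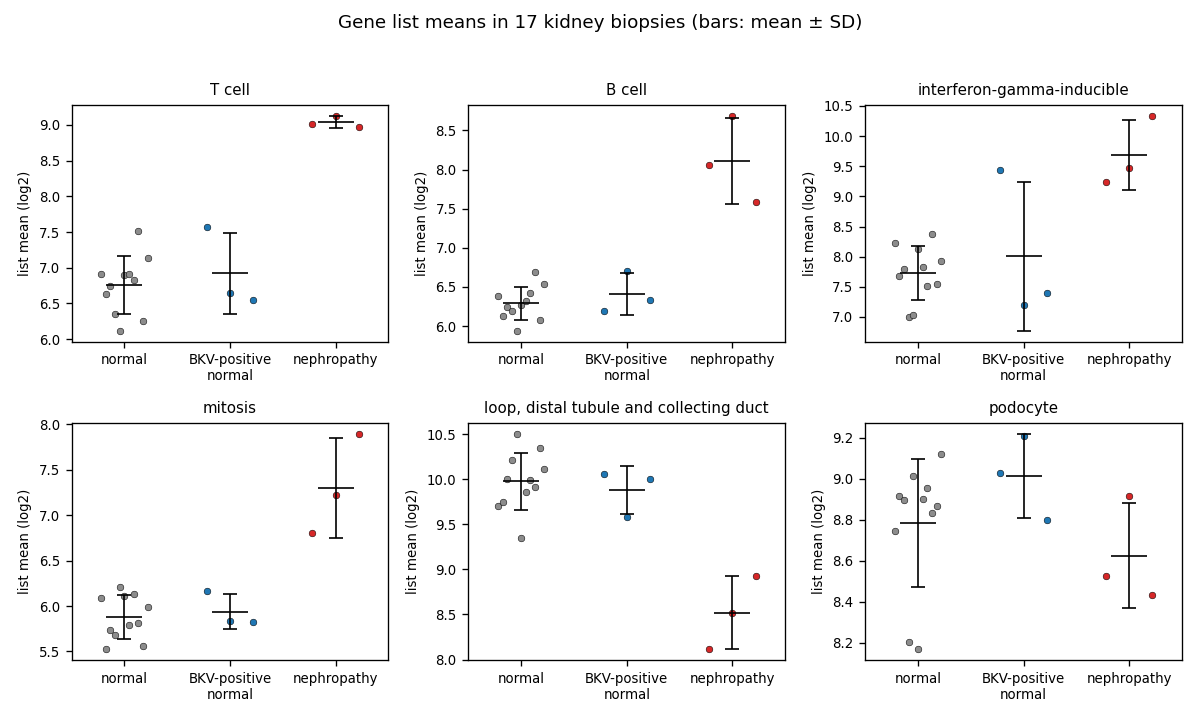
List means per biopsy (log2) for 6 gene lists; each point is a biopsy, bars give the mean and SD, and groups are normal (11), BKV-positive normal (3) and nephropathy (3). In the mitosis panel the lowest nephropathy biopsy, at 6.80, lies above the highest of the other 14, at 6.21, and the podocyte panel shows overlapping groups.

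The second biopsy question was whether a graft of normal histology differs while virus circulates. Between the 3 BKV-positive normal and the 11 normal biopsies, no gene passed in limma (0 of 18394, smallest adjusted p = 0.22), with 2113 at an unadjusted p under 0.05 where 919.7 are expected with no effect. The smallest p belonged to IL5, at 4.26 ± 0.10 against 3.87 ± 0.06, which did not pass and lies low on the array's scale. STEAP3, a metalloreductase of iron uptake, was 0.51 ± 0.09 higher, CHCHD5 0.48 ± 0.10, NXPE1 0.49 ± 0.09, LDHC 1.30 ± 0.26, ZSWIM2 0.39 ± 0.08 and the pseudogene OR52K3P 0.89 ± 0.18, while the differences of ZFP14, ABITRAM and the proteasome chaperone PSMD5 were −0.57 ± 0.11, −0.58 ± 0.12 and −0.86 ± 0.17; none of these passed. No list passed either, nor in camera with an estimated correlation (3 with the preset one). The lowest p was that of the extracellular matrix list, at 8.87 ± 0.15 in BKV-positive normal and 9.41 ± 0.46 in normal biopsies (difference −0.54, lower in 3 of 3, p = 0.0659, adjusted p = 0.875, exact permutation test). Its members COL3A1, COL1A2, LUM and DCN differed by −1.07 ± 0.37, −1.04 ± 0.36, −0.67 ± 0.26 and −0.59 ± 0.23. In limma 0 of 19 members passed, over all genes or adjusted over the list alone. The interferon-gamma-inducible and T cell lists were uneven among the 3: BKV-positive normal biopsy 1 lay at 9.43 and 7.58, the others at 7.19 and 7.40 and at 6.64 and 6.55. Without that biopsy 8 genes passed, ZFP14 among those named, and the interferon-gamma-inducible list difference went from 0.27 to −0.44. It was 0.68 and 0.58 without BKV-positive normal biopsies 2 and 3. Without BKV-positive normal biopsy 2, 711 genes had an unadjusted p under 0.05.

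Between nephropathy and BKV-positive normal biopsies, many lymphocyte genes were again higher, and some nephron genes lower (9 of 15 loop to collecting duct and 5 of 18 proximal tubule members). No list passed the permutation test, which cannot pass with 3 against 3, and 1 passed in camera with an estimated correlation. In limma 1969 genes rose and 1762 fell, and by more than 2-fold 762 rose and 309 fell. Without BKV-positive normal biopsy 2, 1153 rose and 585 fell. Without nephropathy biopsies 1, 2 and 3 in turn, 1536, 1491 and 1400 rose and 955, 1019 and 911 fell. CXCL13 was 5.00 ± 0.46 higher (higher in 3 of 3, adjusted p = 7.58e-06, with 2.08% of genes below its level in BKV-positive normal biopsies). JCHAIN was 3.93 ± 1.06 higher, IL7R 3.71 ± 0.62, MS4A1 3.53 ± 0.69, the innate iron-binding protein LTF 3.52 ± 0.73, CD79A 3.44 ± 0.44, CD180, a surface receptor of B cells, 3.37 ± 0.36, PLAC8 3.35 ± 0.51, TRAT1 3.26 ± 0.54, GPR174 3.16 ± 0.64, CCR7 3.11 ± 0.30 and CD3G 3.09 ± 0.60. The differences of CXCL13, CD180 and TRAT1 may understate the rise, since all of them lie in the dimmest 25% of genes in BKV-positive normal biopsies. The largest falls were in EGF (−3.58 ± 0.73), SLC7A13 (−3.49 ± 0.92), UPP2 (−3.14 ± 0.51), GSTA2 (−2.71 ± 0.82), PLG (−2.66 ± 0.72), F11 (−2.61 ± 0.44), SLC23A3 (−2.58 ± 0.60), AFM (−2.44 ± 0.61), TMEM207 (−2.41 ± 0.64), HRG (−2.34 ± 0.56), APOH (−2.33 ± 0.71) and FAM151A (−2.27 ± 0.74). PLG, F11, AFM, HRG and APOH encode plasma proteins best known from the liver.

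Among the lists, all 14 T cell members rose, and so did 10 of 11 B cell, 14 of 16 macrophage, 17 of 20 mitosis, 19 of 25 DNA replication and 17 of 23 type I interferon-stimulated members. Adjusted over the list alone the counts were 14, 10, 15, 18, 21 and 19. Of the interferon-gamma-inducible members 10 of 13 rose (13 adjusted over the list alone), among them GBP5 by 2.80 ± 0.66, IDO1 by 2.26 ± 0.67, IRF1 by 1.58 ± 0.38 and CIITA by 0.70 ± 0.19. Of the loop, distal tubule and collecting duct members 9 of 15 fell (11 adjusted over the list alone), and of the proximal tubule members 5 of 18 (10 adjusted over the list alone), with MIOX at −1.88 ± 0.52, G6PC1 at −2.13 ± 0.70, FBP1 at −1.42 ± 0.45 and GATM at −0.79 ± 0.25. Of 19 extracellular matrix members 9 rose (11 adjusted over the list alone), with VCAN higher by 2.88 ± 0.59, LUM by 1.41 ± 0.32, TGFBI by 1.28 ± 0.28 and TGFB1 by 0.99 ± 0.22. Of 18 tubular injury members 8 rose (9 adjusted over the list alone), with LCN2 higher by 1.93 ± 0.31, CD44 by 1.75 ± 0.23, TIMP1 by 1.58 ± 0.24 and CXCL16 by 1.36 ± 0.22.

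The list test cannot pass here, since 0.1 is the smallest p that 3 against 3 allows, and the smallest adjusted p was 0.14. In camera 26 lists passed with the preset correlation and 1, inflammatory NF-kB, with an estimated one (adjusted p = 0.0422). For the T cell, B cell and mitosis lists the adjusted p = 0.0748, 0.0696 and 0.0892 with an estimated correlation. The groups did not overlap in 7700 genes, 41.9% of those tested, where chance gives 10%. The gene count was 1738 without BKV-positive normal biopsy 2 and 2311 without nephropathy biopsy 3. Of 43 genes followed, 16 lost their call when 1 biopsy was left out, 13 of them without BKV-positive normal biopsy 2. The 16 were AFM, APOH, CIITA, FAM151A, FBP1, G6PC1, GATM, GBP5, GSTA2, IDO1, IRF1, JCHAIN, MIOX, PLG, SLC7A13 and TMEM207.

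The nephropathy calls against the 2 kinds of comparison biopsy overlapped in 1641 genes that rose and 1036 that fell, where independent lists of these sizes share 241 and 173.1. Both comparisons use the same 3 nephropathy biopsies, so the overlap is not independent evidence. Across genes, the log2 differences of nephropathy and of BKV-positive normal biopsies, both against the normal biopsies, correlated at r = 0.067 (Spearman's rho 0.0116). With no effect simulated, the shared normal biopsies alone gave 0.249 ± 0.239 (100 draws), and with the normal biopsies divided between both comparisons the mean was 0.00393. The covariance was 0.00716, against 0.00699 simulated. The correlation was −0.0921 without BKV-positive normal biopsy 1 and 0.2 without BKV-positive normal biopsy 2, and without any other single biopsy it lay between these values. Genes are not independent replicates in such a correlation.

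In blood, the question was which transcripts mark viremia and whether they change ahead of it. No gene passed in limma between 19 samples at viremia and 14 controls (0 of 18394, smallest adjusted p = 0.83), and 908 had an unadjusted p under 0.05, where 919.7 are expected with no effect. That count was 1591 without control 3, 711 without control 11 and 674, the lowest, without viremia sample 12. The genes with the smallest p included several of cytotoxic lymphocytes. GNLY, the granule protein granulysin, lay at 10.61 ± 0.53 at viremia and 9.79 ± 0.51 in controls (difference 0.82 ± 0.20, above the control mean in 18 of 19). NKG7 differed by 0.72 ± 0.19 and the effector lymphocyte chemokine receptor CX3CR1 by 0.78 ± 0.20, above the control mean in 17 and 19 of 19. JCHAIN differed by 1.62 ± 0.43 with a wide spread at viremia (8.02 ± 1.62, against 6.39 ± 0.54 in controls, and above the control mean in 17 of 19). The others were INSIG1 (0.39 ± 0.09, higher in 19 of 19), HEG1 (0.52 ± 0.13), OSBPL5 (0.33 ± 0.09), PCK2 (0.19 ± 0.05), and the pseudogenes NUDT16L2P (−0.50 ± 0.12) and USP32P1 (−0.50 ± 0.13), none of which passed.

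No list passed at viremia. The plasma cell list came closest, at 7.11 ± 0.28 against 6.84 ± 0.16 (difference 0.28, higher in 17 of 19, p = 0.00202, adjusted p = 0.0707, permutation test with 100000 resamples). In limma 0 of 9 members passed over all genes and 2 adjusted over the list alone. JCHAIN carried much of the difference, which was 0.11 over the other 8 members (higher in 14 of 19, p = 0.0417, permutation test, not adjusted), with a median member at 0.10. Beside JCHAIN, MZB1 differed by 0.17 ± 0.06, TNFRSF17 by 0.28 ± 0.13 and CD38 by 0.40 ± 0.19. The plasma cell list passed without viremia sample 1 (0.29, adjusted p = 0.0462), 7 (0.30, 0.0224), 9 (0.30, 0.0333) or 15 (0.29, 0.0466) and without control 5 (0.31, 0.0147) or 14 (0.28, 0.0455), permutation tests.

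The NK cell list differed by 0.41 (higher in 14 of 19, adjusted p = 0.127), and by 0.46 without control 14, where it passed (adjusted p = 0.0455). Members with the smallest p were FGFBP2 at 1.00 ± 0.30, CD160 at 0.68 ± 0.27, SH2D1B at 0.57 ± 0.24 and XCL1 at 0.53 ± 0.21. None of its 11 members passed over all genes and 1 did adjusted over the list alone. The cytotoxic list differed by 0.47 (higher in 14 of 19, adjusted p = 0.172), with KLRD1 at 0.71 ± 0.24 and GZMB at 0.54 ± 0.20. In limma 0 of 15 members passed over all genes and 6 adjusted over the list alone, all higher. The glucocorticoid-responsive list differed by −0.29 (lower in 14 of 19, adjusted p = 0.172), with ZBTB16 at −0.56 ± 0.23, DDIT4 at −0.42 ± 0.21, PER1 at −0.38 ± 0.18 and KLF9 at −0.19 ± 0.08. The inhibitory receptor list differed by 0.30 (higher in 15 of 19, adjusted p = 0.186), with TOX at 0.47 ± 0.20, CD244 at 0.36 ± 0.16, EOMES at 0.34 ± 0.17 and HAVCR2 at 0.24 ± 0.13. In both lists 0 members passed over all genes or adjusted over the list alone. The type I interferon-stimulated list lay at 8.82 ± 0.93 and 8.36 ± 0.87 (difference 0.45, higher in 12 of 19, adjusted p = 0.529), with EPSTI1 at 0.77 ± 0.39, OAS2 at 0.54 ± 0.31, OAS1 at 0.55 ± 0.32 and XAF1 at 0.47 ± 0.29. None of its 23 members passed over all genes or adjusted over the list alone. The T cell, mitosis, neutrophil and B cell lists differed by 0.31, 0.24, −0.11 and −0.20, and did not pass. The mitosis difference was 0.14 without viremia sample 5, 0.16 without sample 10 and 0.05 without both, and the neutrophil difference −0.06 without sample 5 and −0.07 without sample 12. In camera 17 lists passed with the preset correlation and 0 with an estimated one.

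**Figure D3:**
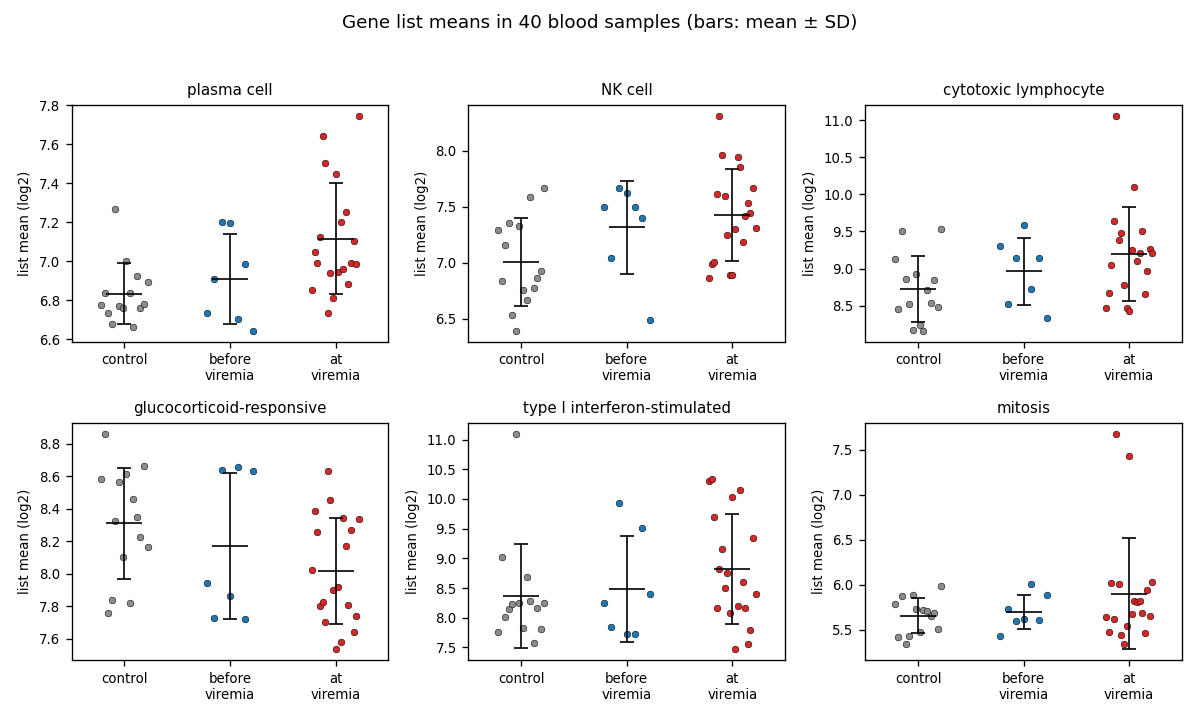
List means per blood sample (log2) for 6 gene lists; each point is a sample, bars give the mean and SD, and groups are control (14), before viremia (7) and at viremia (19). The groups overlap in every panel, and in the mitosis panel viremia samples 5 and 10, at 7.68 and 7.43, lie above all others.

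Blood taken before viremia showed no gene past the threshold against controls (limma, 0 of 18394, smallest adjusted p = 1.00), and 85 genes had an unadjusted p under 0.05, where 919.7 are expected. That count was 170 without before-viremia sample 7 and 142 without control 11. The smallest p belonged to COX15, which assembles cytochrome oxidase, at 7.95 ± 0.14 before viremia (n = 7) and 8.21 ± 0.20 in controls (lower in 7 of 7). The others with the smallest p were CLDN7 (0.16 ± 0.06), CENPV (−0.22 ± 0.08), OR4A15 (−0.17 ± 0.06), ADAMTS18 (−0.17 ± 0.06), NUDC (−0.22 ± 0.08), OR2AK2 (−0.40 ± 0.15), DNAJB13 (0.17 ± 0.07), CXorf58 (−0.16 ± 0.06) and CNR1 (−0.30 ± 0.12), none of which passed. No list passed, and the smallest p was that of the NK cell list (difference 0.31, higher in 6 of 7, p = 0.115, adjusted p = 0.96, exact permutation test). Its members with the smallest p were KLRF1 at 0.64 ± 0.42, FGFBP2 at 0.46 ± 0.40, XCL1 at 0.45 ± 0.27 and KLRB1 at 0.39 ± 0.29, and 0 of 11 passed over all genes or adjusted over the list alone. The cytotoxic and plasma cell lists differed by 0.25 and 0.08 and did not pass. The cytotoxic difference was 0.14 without before-viremia sample 4, and the plasma cell difference 0.03 without sample 3 or 4 and 0.12 without sample 7. In camera 3 lists passed with the preset correlation and 0 with an estimated one.

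Between blood at viremia and before viremia no gene passed either (limma, 0 of 18394, smallest adjusted p = 1.00), and 209 had an unadjusted p under 0.05, where 919.7 are expected. That count was 462, 321, 129 and 134 without before-viremia samples 1, 4, 5 and 7, and 348 without control 11. In the 5 pairs of samples with 1 code number, with that number as a block, 0 passed and 265 had an unadjusted p under 0.05. The smallest p belonged to PCDH18, a protocadherin, at 4.22 ± 0.09 at viremia (n = 19) and 4.37 ± 0.06 before (n = 7), and lower in 18 of 19. The others were HTR3C (−0.20 ± 0.06), CBX6 (0.20 ± 0.06), DNAJB13 (−0.20 ± 0.06), LOXHD1 (−0.55 ± 0.18), PCK2 (0.19 ± 0.06), IFT43 (0.21 ± 0.07), ME1 (−0.46 ± 0.15), DRAP1 (0.40 ± 0.14) and DCBLD2 (−0.24 ± 0.08), none of which passed. For ME1, before-viremia sample 1 lay at 7.00 and the others between 5.27 and 5.80, so that sample carries part of its difference. The interferon-gamma-inducible list had the smallest list p, at 7.74 ± 0.27 and 7.54 ± 0.16 (difference 0.20, higher in 16 of 19, p = 0.0854, adjusted p = 0.937, exact permutation test), with GBP5 at 0.65 ± 0.29, WARS1 at 0.44 ± 0.20, IRF1 at 0.28 ± 0.15 and IL18BP at 0.12 ± 0.06. None of its 13 members passed over all genes or adjusted over the list alone. The plasma cell list differed by 0.20 and did not pass. The list tests of this comparison permuted all samples freely and did not take the 5 pairs of 1 code number into account. In camera 12 lists passed with the preset correlation and 0 with an estimated one.

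Across genes, the log2 differences at viremia and before viremia, both against the controls, correlated at r = 0.49 (Spearman's rho 0.49). The shared controls alone gave 0.462 ± 0.225 in 100 draws with no effect, of which 51 were as high. Draws that kept the 5 pairs of 1 code number across both groups gave 0.448 ± 0.224, with 50 as high. With the controls divided between both comparisons the mean was −0.107. The correlation was 0.287 without before-viremia sample 1 and 0.317 without before-viremia sample 4. Genes are not independent replicates here. The covariance, 0.00536, lay below the simulated 0.00713.

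The last comparison set the tissues side by side, each in its own fit. The log2 differences of nephropathy against normal biopsies and of blood at viremia against controls correlated across 18394 genes at r = 0.281 (Spearman's rho 0.267), and 0 of 100 draws with permuted blood labels reached it in size (mean 0.0131 ± 0.142). Without control blood array 11 the correlation was 0.179, and 11 of 100 draws reached it in size (mean 0.0148 ± 0.121), so the excess over chance depends on that array. Of the 2251 genes that rose in nephropathy, 69.4% had a difference above 0 in blood at viremia, against 45.5% of all genes, with a median of 0.06. In draws with permuted blood labels 3 of 100 gave as high a share and 0 as high an excess over all genes. Without control blood array 11 the share was 61.9%, against 49.2% of all genes, with 9 and 17 of 100 draws as high, so this excess depends on that array too. The share was 61.4% before viremia, against 50.9% of all genes, and 61.7% in BKV-positive normal biopsies, against 57.5% of all genes. The BKV-positive share uses the normal biopsies of the nephropathy comparison. With those divided between both comparisons it averaged 59.8%, against 57.2% of all genes, and exceeded the share of all genes in 63 of 100 draws. Whether these shares differ between comparisons was not tested, and none of these genes passed in blood. Of the 17 biopsies 11 have a blood sample of the same code number. If that number names recipients, which is not stated, some gave both tissues, and the tissues are not fully independent.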

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

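Tests chosen only after the result was seen are those of dilution by leukocytes, less medulla, a single biopsy carrying the rise, the 6 brighter cell cycle genes, control blood array 11 (its blood splits included) and the granulocyte share.

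In blood before viremia, 54 values (the 35 list means and the named genes) were scanned for a sample far from the other 6. In 2 of them a sample stood apart, where 2.7 are expected by chance at 1 in 20. OR2AK2, an olfactory receptor gene, was at 5.35 in before-viremia sample 3 and between 4.55 and 4.78 in the others. ME1, the cytosolic malic enzyme, was at 7.00 in before-viremia sample 1 and between 5.27 and 5.80 in the others. Among 9565 probe sets that the annotation gives several genes or none, 775 passed the threshold between nephropathy and normal biopsies in limma, 421 of them higher, and these transcripts were not analysed here.

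Random splits of the samples make chance an unlikely source of the 4058 genes that separated nephropathy from normal biopsies. In these, 1 of 100 splits, the real one, reached that count, and the highest other gave 7. For nephropathy against BKV-positive normal biopsies the 10 splits are too few for a share under 0.05, with 3731 genes in the real split, the 1 that reached that count, and 0 in the highest other. Chance is not excluded for the counts at an unadjusted p under 0.05 in the other comparisons. For viremia against control, 27 of 100 splits gave at least the real 908, and the highest other gave 5470. For before viremia against control, 100 of 100 gave at least the real 85, and the highest other gave 5892. For viremia against before viremia, 85 of 100 gave at least the real 209 (highest other 2389), and 28 of 32 exchanges within the 5 pairs of 1 code number did (highest other 879). For BKV-positive normal against normal biopsies, 9 of 100 gave at least the real 2113, and the highest other gave 3960. Splits of the blood with several times the real count point to a structure of the samples, whose source is not known. Without control blood array 11 such splits still occurred, with 711, 142 and 348 genes in the real split and 4519, 3321 and 3715 in the highest other, in the order above, so that array alone does not make them.

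The first pattern is the fall of loop, distal tubule and collecting duct genes in nephropathy. Dilution of kidney RNA by leukocytes would lower all kidney cells alike, but the list fell below the podocyte list by −1.30 (exact permutation p = 0.00275, the smallest possible; SD 0.34 in normal biopsies), which argues against dilution as the whole cause. Cores holding less medulla would not lower the proximal tubule list, which is mainly cortical, but its difference of −0.76 (exact permutation p = 0.0962, SD 0.73) did not pass, and with single biopsies left out it passed after adjustment only without normal biopsy 6 (−0.96, adjusted p = 0.0051), so less medulla and a loss of distal tubule transcripts cannot be told apart here. The mean of 5 distal convoluted tubule members, also cortical, differed by −1.28 (exact permutation p = 0.033), but they belong to the list that fell and were chosen after their values were seen, so they decide nothing. A loss of distal tubule transcripts with the virus infection, which the design names, stays open as a hypothesis and was not tested.

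The second pattern is the rise of cell cycle genes in nephropathy. It did not come from a single biopsy, since the lowest nephropathy biopsy (6.80) lay 0.59 above the highest of the other 14 (6.21). If dividing leukocytes came in proportion to T cells, as in the other 14 biopsies, the mitosis list would rise by 0.36, at most 1.08 at the upper end of the 95% interval, against an observed 1.41, a bound set before the slope was computed. Of the 20 members 14 lie in the dimmest 25% of genes (below 6.37) in those biopsies. The other 6 gave an upper end of 0.89 against a rise of 1.18. Both upper ends carry only the uncertainty of the slope and take the observed rise as exact. The mitosis list had an SD of 0.55 over the nephropathy biopsies, so its rise is not clearly separated from the upper end. The line is also extended beyond the T cell levels of the other 14 biopsies (7.58 at most, against 8.97 or more in nephropathy). The test therefore does not decide whether this proportion is the whole cause, which stays open. Leukocytes dividing more than in the other biopsies, and infected tubule cells driven into the cell cycle, stay open as hypotheses, either of which may contribute, and were not tested.

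The third pattern is the higher level of cytotoxic lymphocyte genes in blood at viremia, which did not pass adjustment. Control blood array 11 does not account for it, since the list difference was 0.46 (SE 0.19) without that array and 0.47 with it. A lower granulocyte share would raise B cell genes as well. The cytotoxic list rose above the B cell list by 0.67 (SE 0.26, permutation p = 0.0137), and by 0.74 without array 11 (p = 0.00767). The B cell list itself was lower at viremia, while the T cell list was higher. A loss of B cells would widen this gap under a lower granulocyte share too, so the gap does not decide on that share. The limit below which that test would have favoured a granulocyte share was widened from 0.1 to 1 SE after a first run, and the difference lay above both. A response of cytotoxic cells to the virus may underlie the difference, but as a hypothesis found and tested on the same samples, and B cell loss or a difference in drug treatment stays open and was not tested.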

How the results depend on the processing

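Tests chosen only after the result was seen are leaving out control blood array 11, leaving out normal biopsy 6 and limma on list means.

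In blood the count of genes past the threshold was 0 in limma under all settings run, leaving out each sample and the blocks on code numbers included (at an unadjusted p under 0.05 as reported, 908 at viremia and 85 before viremia against control, and 209 between them). Those counts ranged from 674 to 1591, from 84 to 170 and from 129 to 462 when each sample was left out. They were 872, 433 and 527 with array quality weights and 1187, 112 and 800 with the title number as a block. With the code number as a random block they were 1010, 122 and 317, and with repeated quantile normalization 906, 167 and 243 (the causes were not tested). Between nephropathy and normal biopsies, 4058 genes passed as reported, 2159 with the title number as a block (1993 shared) and 7000 with array quality weights (the cause was not tested). Leaving out each biopsy gave 2601 (without nephropathy biopsy 2) to 4776 (without normal biopsy 6). The count was 3086 without the normal biopsies whose code number recurs in blood of the BKV groups, which leaves fewer samples. For BKV-positive normal against normal biopsies the range was 0 to 8 (8 without BKV-positive normal biopsy 1; the cause was not tested). For nephropathy against BKV-positive normal biopsies it was 1738 (without BKV-positive normal biopsy 2) to 3645, and 4357 without normal biopsy 6. Between BKV-positive normal and normal biopsies, 2113 genes had an unadjusted p under 0.05 as reported and 1204 with array quality weights.

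Lists past the threshold with camera's preset correlation numbered 17 for viremia against control, 3 for before viremia against control, 12 for viremia against before viremia, 3 for BKV-positive normal against normal biopsies and 26 for nephropathy against BKV-positive normal biopsies, where the permutation test gave 0 in each. With an estimated correlation camera gave 15 for nephropathy against normal biopsies, where the permutation test gave 24, and 1 against BKV-positive normal biopsies, where limma on list means gave 27. That permutation test cannot pass with 3 against 3, and for the other differences the cause was not tested. Leaving out each sample gave 0 to 2 lists for viremia against control (2 without control 14) and 23 to 28 for nephropathy against normal biopsies.

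Reversed values, for which the cause was not tested, were few. Between nephropathy and normal biopsies the eosinophil list was at −0.00913 by the median. Leaving out each biopsy, CA1 ranged from −0.12 (without nephropathy biopsy 3) to 1.12, and TCF21 from −0.40 to 0.12 (without nephropathy biopsy 3). In the same way CR2 reached −0.21 and 0.61, and FDCSP reached −0.0772 and 0.49, the lowest without nephropathy biopsy 2. For BKV-positive normal against normal biopsies the interferon-gamma-inducible list ranged from −0.44 (without BKV-positive normal biopsy 1) to 0.68. The correlation of nephropathy and BKV-positive effects ranged from −0.0921 (without BKV-positive normal biopsy 1) to 0.2004 (without BKV-positive normal biopsy 2).

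Of the values of single genes under all settings, 3923 of 4035 for nephropathy against normal biopsies kept direction and side of the threshold, 83 no longer passed, 25 newly passed and 4 reversed. Against BKV-positive normal biopsies 585 of 643 did, with 52 no longer and 6 newly past. In blood all 1394, 456 and 526 did, in the order above. No blood gene passed under any setting, so the side of the threshold was the same throughout and the tally speaks to direction only. For lists described in nephropathy against normal biopsies 694 of 735 did, with 15 no longer and 25 newly past and 1 reversed.

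Low signal over background limits what arrays can show for dim genes. Without the dimmest 25% of genes, 3671 of 13795 passed between nephropathy and normal biopsies, and 14 of 20 mitosis members lay in that dimmest part in the other 14 biopsies. A block on the code number could not be estimated in biopsies, and the test of a difference between tissues was not run.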

Other observations

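Tests chosen only after the result was seen are those of the genes of lymphoid tissue in the last paragraph, except CCL19.

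Other leukocyte and stress lists were also compared between 3 nephropathy and 11 normal biopsies (exact permutation tests; limma for members). All 4 plasmacytoid dendritic cell members rose, over all genes and adjusted over the list alone, among them the surface receptor CLEC4C by 1.51 ± 0.20 and IL3RA by 1.04 ± 0.13, and the list difference was 1.08 (higher in 3 of 3, smallest possible p). Of 12 neutrophil members 9 rose (10 higher and 1 lower adjusted over the list alone), such as MNDA by 2.02 ± 0.17 and CSF3R by 1.09 ± 0.12, with a list difference of 0.85 and the smallest possible p. Of 9 complement members 6 rose, over all genes and adjusted over the list alone, with C3 at 2.53 ± 0.54, C2 at 1.92 ± 0.34, C1S at 1.25 ± 0.24 and C1R at 1.00 ± 0.18. The complement list difference was 0.99 with the smallest possible p, and in camera its adjusted p = 0.122 with an estimated correlation. Of 10 immediate early and heat shock members 6 rose, over all genes and adjusted over the list alone, such as the transcription factors JUNB by 1.26 ± 0.15 and EGR1 by 1.20 ± 0.21. Its list difference was 0.54 with the smallest possible p, and in camera its adjusted p = 0.0635 with an estimated correlation. Of 15 ribosomal protein members 7 rose, over all genes and adjusted over the list alone, with RPS3 at 0.56 ± 0.09 and RPS27 at 0.52 ± 0.09. Its list difference was 0.25 with the smallest possible p, and in camera its adjusted p = 0.124 with an estimated correlation.

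Other lists did not pass in these biopsies. Of 7 mast cell and basophil members 4 rose and 1 fell (4 and 2 adjusted over the list alone), with the mast cell protease CPA3 at 1.83 ± 0.36 and GATA2 at −0.48 ± 0.15. The mast cell list difference was 0.33 (adjusted p = 0.0615, exact permutation test) and passed without normal biopsy 6 (0.39, adjusted p = 0.0051). Of 13 neutrophil precursor granule members 2 rose, LTF by 3.16 ± 0.58 and LCN2 by 1.41 ± 0.25, both also made by injured tubules, while the median member differed by −0.02. That list's mean differed by 0.40 (adjusted p = 0.0629, exact permutation test) and passed without normal biopsy 1 (0.44, adjusted p = 0.0306), 5 (0.34, 0.0441) or 8 (0.43, 0.0441). Of 7 eosinophil members 2 rose (2 higher and 1 lower adjusted over the list alone), CLC by 1.10 ± 0.13 and SMPD3 by 0.68 ± 0.08 (list difference 0.16, adjusted p = 0.093, exact permutation test; 0.10 without nephropathy biopsy 1). Of 11 erythroid members 2 fell, SELENBP1 (−1.24 ± 0.23) and SLC4A1 (−1.29 ± 0.39), both also expressed in kidney tubules, with a list difference of −0.21 (adjusted p = 0.0962, exact permutation test) that passed without nephropathy biopsy 3 (−0.39, adjusted p = 0.0195) and was −0.07 without nephropathy biopsy 1. Of 12 platelet members 2 rose, ITGB3 by 1.25 ± 0.29 and GP1BA by 0.56 ± 0.11 (list difference 0.05, adjusted p = 0.39, exact permutation test; 0.02 and 0.10 without nephropathy biopsies 1 and 3). Of 8 glucocorticoid-responsive members 2 fell (3 adjusted over the list alone), ERRFI1 (−1.62 ± 0.56) and KLF9 (−0.62 ± 0.16). Its list difference was −0.62 (adjusted p = 0.0641, exact permutation test) and passed without nephropathy biopsy 1 (−0.88, adjusted p = 0.0374) or normal biopsy 9 (−0.71, adjusted p = 0.0204). In the precursor granule, erythroid and platelet lists the counts adjusted over the list alone were the same. None of 8 smooth muscle members passed, over all genes or adjusted over the list alone (list difference −0.66, adjusted p = 0.312, exact permutation test), with MYH11 at −1.22 ± 0.58. The smooth muscle difference was −0.39 without normal biopsy 3. Without 1 nephropathy biopsy, SLC4A1 and GATA2 (biopsy 1), KLF9 and GATA2 (biopsy 2 or 3) and ERRFI1 (any of the 3) lost their calls, among 16, 13 and 7 of 163 genes. ERRFI1 also lost its call without normal biopsies 1, 2, 3, 4, 5, 7, 8 or 10.

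Single samples stood apart in some lists. Viremia samples 5 and 10 had mitosis list means of 7.68 and 7.43. The type I interferon-stimulated list was at 11.09 in control blood 6. The smooth muscle list was at 11.74 and 10.34 in normal biopsies 3 and 6.

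Beside CXCL13, the chemokine CCL19, which draws cells bearing CCR7, was among the 12 largest rises in nephropathy, by 3.43 ± 0.37. Of other genes of lymphoid tissue, looked at after these values were seen, CCL21 rose by 2.13 ± 0.42, the CXCL13 receptor CXCR5 by 1.99 ± 0.23 and the mature dendritic cell gene LAMP3 by 2.52 ± 0.22. LTB, CR2 and FDCSP did not pass, at 0.32 ± 0.14, 0.30 ± 0.90 and 0.24 ± 0.18, the latter 2 being genes of follicular dendritic cells. CR2 and FDCSP differed by −0.21 and −0.08 without nephropathy biopsy 2. Against BKV-positive normal biopsies CCL21 did not pass (1.52, adjusted p = 0.0502) and did without nephropathy biopsy 3.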
